A study of Mus musculus with 12 samples.

How the data were processed

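Liver RNA of 12 mice was analysed, 4 per group. The count values are raw whole numbers per Ensembl gene, per the file headers, for 8 libraries in each of 2 deposited tables, and the 4 HFD libraries are in both. HISAT2 2.0.5, StringTie 1.3.2d and HTSeq 0.6.0 were used, per the submitters' processing notes, which give no settings; the counting setting for strand and the annotation release are not given in the sources used here. The deposited log2 fold change, the deposited fold change (a ratio) and the deposited p-value and adjusted p-value of each gene are the authors' own comparison, per the file headers, which do not name the test. The labels list builds mm8 and mm9, but the positions in the tables match GRCm38: of 25113 identifiers also in the GENCODE M21 annotation, 23225 (92.5%) have the same position.

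The 2 tables were joined by gene identifier. They share 22657 genes, and 1389 are listed only with fenofibrate and 1118 only with the diet; each table lists genes with at least 1 count, so a gene missing from a table was given counts of 0 there. The HFD counts differed in 0 cells between the tables. Dates stood in place of 22 symbols in the diet table, and these were restored by identifier. No per-sample column was left unassigned.

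Counts were analysed with edgeR 4.0.16 in R 4.3.3. Genes passing filterByExpr were kept (13477 of 25164), library sizes were scaled by TMM, and a quasi-likelihood model with 1 coefficient per group was fitted to all 12 libraries. Genes with a Benjamini-Hochberg adjusted p under 0.05 are said to have risen or fallen. Log2 fold changes use a prior count of 0.125, and levels of single genes are TMM-scaled CPM. Marker sums and the values of Pnlip, Cpa1, Xist and Ddx3y are CPM of the total counts without TMM scaling. The common biological coefficient of variation was 0.155. Total counts ran from 15797016 to 18514481 per library. Between libraries of a group, chi-square per gene was 15.1 to 42.2 over 18 pairs, so the spread between mice exceeded counting error. Replicate numbers were not taken as pairs: after group means were removed, same-numbered libraries had r from -0.175 to 0.139 (mean 0.003).

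The comparisons, tests, naming rule, 36 gene lists (23 of pathways and 13 of markers) and alternatives other than those named below as added were chosen before the data were examined. In each comparison the text names the 8 rising and 8 falling genes with the largest change that passed, reached a mean of 10 CPM in the higher group, had no overlap between the groups and had a named symbol, up to 4 passing members of each list described (the 2 most abundant where none passed), and a panel of 18 genes, except that some genes under this rule are not reported here. Lists were tested with camera of limma 3.58.1 on voom values with a preset correlation of 0.01, adjusted over the 36 lists, and again with an estimated correlation and with fry. Single values per library were compared by two-sided exact permutation tests of 4 against 4 libraries.

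The steps were tested on simulated counts with 200 changed genes. At 1.5-fold, 2-fold and 4-fold, edgeR recovered 26.9%, 76.1% and 95.5% for the diet (13322 genes), 47.8%, 73.1% and 95.5% for fenofibrate against HFD (13310 genes) and 46.3%, 80.6% and 95.5% for fenofibrate against Control (13329 genes). False calls were 4.3%, 6.5% and 5.7% of calls. Of 200 genes changed 4-fold in HFD alone, 198 were found moved back, and smaller changes were not simulated for this count. Alternatives were DESeq2 1.42.0, limma-voom, other scaling and filters, the 20 most abundant genes left out, only the 8 libraries compared, the replicate number as a block, stricter thresholds, each library left out in turn, other list tests, and the HFD libraries divided between the comparisons. Added after the data were seen were fits without fenofibrate libraries 1 and 3, without these and Control library 2, and with a clock score as a covariate. Cidea was not tested for its low counts.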

Results

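Liver RNA was sequenced from mice of 3 groups, with 4 libraries per group. Control mice ate a normal diet for 14 weeks, HFD mice ate a high-fat diet for 14 weeks, and the HFD plus fenofibrate mice ate the same high-fat diet and received fenofibrate by gavage for the last 4 weeks, after 10 weeks of diet alone. Fenofibrate is a lipid-lowering drug that activates the nuclear receptor PPARA. The study assigned 10 mice to each group. Total counts per library ran from 15797016 to 18514481. Of 25164 genes listed, 13477 were tested and held 99.87% of the counts. Levels below are group means in CPM (read counts scaled to a common library size) ± SD with n = 4 libraries per group. Log2 fold changes are given ± SE, which is the size of the change divided by the square root of the test's F statistic. Positions are those of the deposited tables, which match GRCm38. Every adjusted p is from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment unless another test is named. Nothing in the labels says how cages, dissection or sequencing runs were shared, so the p-values measure the spread between these libraries.

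Markers of other tissues and cell types differed between libraries of one group. The 12 pancreatic acinar markers summed to 2154 CPM in fenofibrate library 1 and to 9.02 to 13.9 CPM in the other fenofibrate libraries. The 6 striated muscle genes summed to 160 CPM in fenofibrate library 1 and 122 CPM in fenofibrate library 3, against at most 1.03 CPM in any other library. Fenofibrate library 1 also held 1193 CPM of erythroid markers, against 203 to 399 CPM in the other fenofibrate libraries. Summed hepatocyte markers were 157470 ± 5825 CPM in Control, 139510 ± 4663 in HFD and 138300 ± 7020 in the fenofibrate group. These marker sums are CPM of the total counts without TMM scaling. Scaling divides by factors of 0.884 to 0.997 in Control, 0.896 to 1.03 in HFD and 0.99 to 1.16 with fenofibrate. The near-equal sums of HFD and fenofibrate thus do not show equal scaled levels. The drop from Control to HFD gave p = 0.0286 in a two-sided exact permutation test, the smallest p that 4 against 4 libraries allow, and 0.103 after adjustment over 18 measures. Mitochondrially encoded genes took 9.64% ± 0.454 of counts in Control, 9.27% ± 0.881 in HFD and 7.72% ± 0.705 with fenofibrate (exact permutation p = 0.0286 against HFD, 0.172 adjusted).

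The first comparison asked what the high-fat diet changed in the liver. The amino acid catabolism genes Got1 and Asl and the drug-metabolism gene Cyp3a11 were lower in HFD livers, while Mup17, the desaturase gene Scd1 and the clock-output gene Dbp were higher. Mup17 (ENSMUSG00000096688, chromosome 4, 61591929 to 61595871), a major urinary protein gene, stood at 972 ± 271 CPM in HFD and 39.7 ± 5.17 in Control (log2 fold change 4.62 ± 0.33, adjusted p = 8.2e-07). Cyp3a11 (ENSMUSG00000056035, chromosome 5, 145854430 to 145879960), an abundant drug-metabolizing cytochrome P450, fell from 10745 ± 951 to 1757 ± 257 CPM (-2.61 ± 0.18, adjusted p = 6.2e-07). Mt1 (ENSMUSG00000031765, chromosome 8, 94179082 to 94180327), a metallothionein, fell from 319 ± 94.1 to 9.84 ± 1.76 CPM (-5.02 ± 0.32, adjusted p = 5.5e-07). In all, 826 genes rose and 895 fell, of which 185 and 217 changed at least 2-fold. The count of falling genes was 554 without Control library 1, 580 without HFD library 2 and 562 without HFD library 4, and that of rising genes was 550 without HFD library 4.

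The largest rises under the naming rule were in Cyp2b9 (6.05 ± 0.94), Mup17, Dbp (3.67 ± 0.53), Rgs16 (3.56 ± 0.61), Rad51b (3.44 ± 0.45), Mup15 (3.28 ± 0.35), Hsd3b5 (3.12 ± 0.35) and Serpina7 (2.96 ± 0.33). Cyp2b9, a cytochrome P450 that is female-biased in mouse liver, was at 13.6 ± 15.7 CPM in HFD and 0.2 ± 0.2 in Control, where 13 reads were counted over the 4 libraries. Dbp is a clock-output transcription factor, Rgs16 a regulator of G-protein signalling, Hsd3b5 a male-biased steroid enzyme and Serpina7 the thyroxine-binding globulin. Adjusted p for these 8 genes lay between 8.2e-07 and 0.0014. The largest falls under that rule were in Cux2 (-5.31 ± 0.47), a female-biased transcription factor at 0.401 ± 0.198 CPM in HFD and 16.3 ± 5.35 in Control, Mt1, the transcript CT010575.3 (-4.26 ± 0.64), Cyp2b10 (-3.11 ± 0.52), Gsta2 (-2.75 ± 0.26), Slc16a5 (-2.73 ± 0.26), Ugt1a9 (-2.73 ± 0.19) and Cyp3a11. Mup, Cyp2b, Gsta and Ugt1a genes have near-identical copies or shared exons among which reads can be split, so their single values are uncertain. Without 1 library, the log2 change of Cyp2b9 was 4.84 (HFD library 3) or 6.97 (Control library 4), that of Rgs16 2.80 (HFD library 2), that of Rad51b 4.41 (Control library 2) and that of CT010575.3 -5.42 (HFD library 2).

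Of 26 genes of amino acid catabolism and the urea cycle, 21 fell and 0 rose (23 and 0 adjusted over the list alone). Got1, an aspartate aminotransferase, fell from 662 ± 134 to 123 ± 30.8 CPM (-2.43 ± 0.24, adjusted p = 1.4e-05). The urea cycle genes Asl (-1.89 ± 0.15) and Ass1 (-1.35 ± 0.14) and the cysteine-forming Cth (-1.57 ± 0.21) fell too. Camera gave the list adjusted p = 1.7e-20, and adjusted p = 0.124 with an estimated correlation. Of 28 xenobiotic metabolism genes, 17 fell and 3 rose (18 and 4 adjusted over the list alone), with Cyp2b10, a target of the nuclear receptor CAR, falling from 764 ± 400.1 to 88.3 ± 50.6 CPM. That list had camera adjusted p = 2.1e-07, and adjusted p = 0.124 with an estimated correlation. Summed hepatocyte markers, of which Cyp3a11 is 1, were lower in the same HFD libraries by the amounts given above. Over the 12 markers, 2 fell and 0 rose, with a median log2 change of -0.075 (camera adjusted p = 0.162, fry adjusted p = 0.0395).

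Of 23 peroxisomal beta-oxidation genes, 10 rose and 0 fell (14 and 0 adjusted over the list alone), among them Acaa1b, a peroxisomal thiolase, from 963 ± 182 to 1820.4 ± 243 CPM (0.92 ± 0.16, adjusted p = 0.00135), Crot (0.86 ± 0.20), Pex11a (0.71 ± 0.14) and Abcd3 (0.62 ± 0.15). Of 22 mitochondrial beta-oxidation and ketogenesis genes, 7 rose and 0 fell (12 and 0 adjusted over the list alone), led by Bdh1, which interconverts ketone bodies (1.26 ± 0.14, adjusted p = 4.0e-05), with Decr1 at 0.66 ± 0.14 and Hadh at 0.59 ± 0.09. Camera adjusted p was 7.8e-07 and 6.5e-07 for these lists, and both had adjusted p = 0.602 with an estimated correlation. Among 24 other PPARA targets, 9 rose and 1 fell (10 and 1 adjusted over the list alone; camera adjusted p = 0.0158, adjusted p = 0.831 with an estimated correlation). Vnn1, a pantetheinase, rose from 33.9 ± 13.4 to 185 ± 49.5 CPM (2.45 ± 0.27) and Fabp1, the liver fatty acid-binding protein, from 1078 ± 394 to 3933 ± 908 (1.87 ± 0.23), while Por, the electron donor of microsomal P450s, fell (-1.66 ± 0.17). The camera call of this list was lost without HFD library 4 (adjusted p = 0.0533).

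Of 25 genes of lipogenesis and triglyceride synthesis, 8 rose and 1 fell (8 and 1 adjusted over the list alone; camera adjusted p = 0.00145, adjusted p = 0.602 with an estimated correlation). Scd1, the main hepatic fatty acid desaturase, rose from 5166 ± 108 to 15616 ± 4983 CPM (1.60 ± 0.28, adjusted p = 0.0016). Of 21 bile acid genes, 8 rose and 6 fell (8 and 7 adjusted over the list alone; camera adjusted p = 0.764), with a median of 0.12 and a mean of -0.02. In that list Akr1c6 rose (1.25 ± 0.18), and the transporter gene Slco1a4 (-2.37 ± 0.27) and Cyp7a1, the rate-limiting enzyme of bile acid synthesis, fell (122 ± 71.1 to 40.3 ± 21.7 CPM, -1.59 ± 0.40, adjusted p = 0.0163). The Cyp7a1 call was lost without Control library 2 (adjusted p = 0.0538) or HFD library 2 (adjusted p = 0.0515). Of 19 genes of gluconeogenesis and glucose handling, 6 rose and 3 fell (7 and 5 adjusted over the list alone; camera adjusted p = 0.879, direction up against a median of -0.06 and a mean of -0.07). The glucose transporter gene Slc2a2 rose (0.84 ± 0.11), and Irs2 (-1.47 ± 0.23) and Igfbp2 (-1.21 ± 0.15) fell.

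The 18 clock genes split into rising and falling members, with 7 up and 5 down (9 and 5 adjusted over the list alone; camera adjusted p = 0.305). Nr1d1, a clock repressor, rose from 11.7 ± 3.72 to 78.2 ± 10.1 CPM (2.74 ± 0.20), and Arntl, the core activator, fell from 31.9 ± 4.88 to 11.2 ± 5.16 CPM (-1.52 ± 0.24). A score made of 4 genes of each arm lay between -2.43 and -1.84 in Control and between -0.168 and 1.90 in HFD libraries. Of 16 male-biased genes, 5 rose and 1 fell (5 and 2 adjusted over the list alone; camera adjusted p = 0.254, with a median of -0.05 against a mean of 0.31 and a test direction of up), including Hsd3b5 and Mup21 (1.67 ± 0.22). Of 9 female-biased genes, 2 rose and 2 fell (2 and 2 adjusted over the list alone; camera adjusted p = 0.528), Cyp2b9 and Rtn4 (0.85 ± 0.17) rising and Cux2 falling. Of 21 interferon response genes, 2 rose and 0 fell (2 and 0 adjusted over the list alone; camera adjusted p = 8.0e-04, adjusted p = 0.834 with an estimated correlation), among them Iigp1, an interferon-induced GTPase (0.95 ± 0.19). Camera called 7 of 36 lists, and 24 of the 35 divisions of the 8 libraries into 4 and 4 called at least as many.

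In the panel of fat-metabolism genes, Scd1 and Cyp7a1 passed as given above. Cd36, a fatty acid transporter, rose from 26.1 ± 1.13 to 50.5 ± 18.3 CPM (0.95 ± 0.21, adjusted p = 0.00895). Srebf1, a lipogenic transcription factor (0.86 ± 0.26, adjusted p = 0.0432), passed narrowly. Not passing were Ppara (0.48 ± 0.17), Pparg (0.52 ± 0.18), Ehhadh (-0.11 ± 0.35), Cyp4a10 (-0.32 ± 0.22), Cyp4a14 (-0.17 ± 0.39), Cpt1a (-0.27 ± 0.12), Pdk4 (-0.82 ± 0.59), Fgf21 (1.05 ± 0.54), Plin2 (0.29 ± 0.23), Cidec (-0.32 ± 0.20) and Fasn (0.35 ± 0.21), with adjusted p from 0.0808 to 0.88. Cidea, with at most 4 counts in a library, was not tested. The call of Srebf1 was lost without Control library 2, 3 or 4, HFD library 2 or 3 or fenofibrate library 3 or 4 (adjusted p from 0.0513 to 0.141), and without fenofibrate libraries 1 and 3 together (0.058). It was also lost with DESeq2 (0.0575), with a filter of at least 1 CPM on average (0.0513) and with only the 8 libraries compared (0.0518), and Ppara passed with no low-count filter (0.0464). Pparg passed without Control library 2 (0.65, adjusted p = 0.0424) or HFD library 1 (0.65, adjusted p = 0.0319). Without Control library 2, in which Pdk4 stood at 111 CPM, Fgf21 passed (1.99, adjusted p = 0.0141), and the log2 changes of Cyp4a14 and Pdk4 were 0.44 and -0.10.

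**Figure D1:**
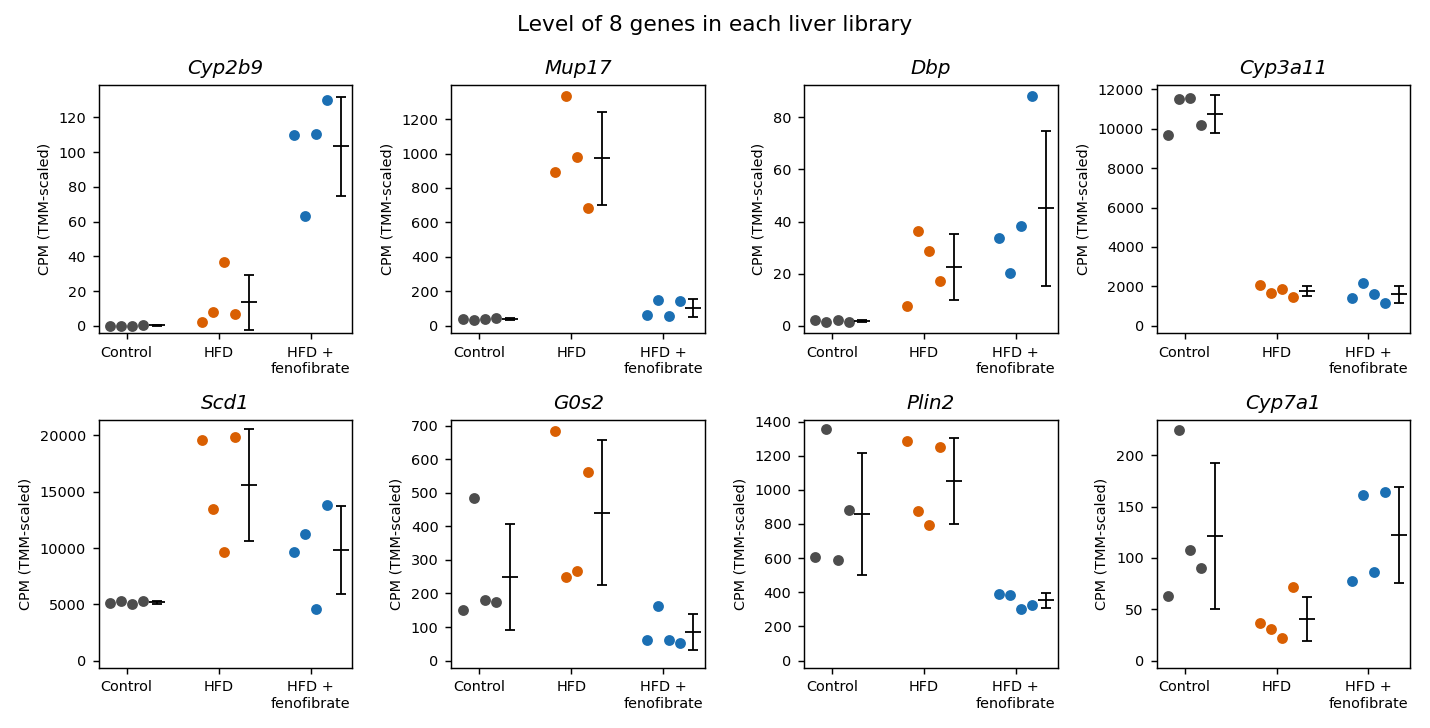
Level of 8 genes in each of the 12 libraries, in TMM-scaled CPM on linear axes. Each point is 1 library, and the black bars give the group mean ± SD with n = 4 per group. Cyp3a11 has a mean of 10745 CPM in Control and lies at or below 2160.2 CPM in every other library, and Mup17 is high in the HFD libraries.

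The next comparison asked what fenofibrate changed in livers of mice kept on the high-fat diet. The lipid droplet genes Plin2 and G0s2, the complement gene C9 and the male-biased gene Mup7 were lower with fenofibrate, and the urea cycle gene Asl was higher. Plin2 (ENSMUSG00000028494, chromosome 4, 86648386 to 86670060), the protein coating hepatic lipid droplets, fell from 1051 ± 252 to 352 ± 42.2 CPM (-1.58 ± 0.24, adjusted p = 0.00139), and G0s2, an inhibitor of the lipase encoded by Pnpla2, from 441 ± 217 to 83.8 ± 53.5 (-2.40 ± 0.46, adjusted p = 0.00483). Cyp7a1 (ENSMUSG00000028240, chromosome 4, 6265612 to 6275633) rose from 40.3 ± 21.7 to 123 ± 46.9 CPM (1.60 ± 0.40, adjusted p = 0.018), a call that was lost without HFD library 1 (adjusted p = 0.0538). In all, 928 genes rose and 888 fell, of which 136 and 118 changed at least 2-fold. The counts of rising and falling genes were 436 and 419 without HFD library 1, 571 and 581 without HFD library 2, 444 and 485 without HFD library 4, 464 and 434 without fenofibrate library 1, and 282 and 328 without fenofibrate library 3. Without fenofibrate libraries 1 and 3, which held the muscle and pancreatic transcripts, they were 55 and 69.

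The largest rises under the naming rule were in Cux2 (4.93 ± 0.47, 0.401 ± 0.198 to 12.5 ± 5.87 CPM), Mt1 (2.98 ± 0.30), Cyp2b9 (2.93 ± 0.53, 13.6 ± 15.7 to 103 ± 28.5 CPM), Cyp2a22 (2.64 ± 0.34), Vldlr (2.23 ± 0.32), the receptor of very-low-density lipoprotein, Lcn2 (2.19 ± 0.34), Slc27a1 (1.92 ± 0.22), a fatty acid transport protein, and Slc16a5 (1.78 ± 0.26). Falls under that rule were largest in Mup17 (-3.24 ± 0.31, 972 ± 271 to 103 ± 51.5 CPM), Mup15 (-2.65 ± 0.34), Hectd2os (-2.58 ± 0.20), Slc22a28 (-2.56 ± 0.24), an organic anion transporter, G0s2, Mup18 (-2.29 ± 0.27), Serpina12 (-2.21 ± 0.30) and Mup2 (-2.17 ± 0.35). Adjusted p for these 16 genes lay between 1.2e-05 and 0.00483. Hectd2os overlaps the gene on the other strand and the counting setting for strand is not given in the sources used here, so its value is uncertain, as are those of the Mup genes, Cyp2b9 and Cyp2a22 with their close copies. The log2 change of Cyp2b9 was 4.15 without HFD library 3, and without fenofibrate libraries 1 and 3 the calls of Cyp2b9 (2.83, adjusted p = 0.0518) and G0s2 (-2.03, adjusted p = 0.121) were lost.

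Of 26 amino acid catabolism and urea cycle genes, 15 rose and 1 fell (17 and 2 adjusted over the list alone). Asl rose from 359 ± 38.3 to 892 ± 197 CPM (1.31 ± 0.15, adjusted p = 2.4e-04), and Got1 from 123 ± 30.8 to 266 ± 78.1 (1.11 ± 0.23), while Otc, another urea cycle gene, fell (-0.64 ± 0.14). Camera adjusted p was 2.2e-09, and the list had adjusted p = 0.449 with an estimated correlation. Of 31 complement and coagulation genes, 10 fell and 0 rose (18 and 3 adjusted over the list alone; camera adjusted p = 8.9e-06, adjusted p = 0.449 with an estimated correlation). C9 (-1.40 ± 0.16, 573 ± 45.3 to 217 ± 54.8 CPM) and C8a (-0.72 ± 0.10), components of the membrane attack complex, and the mannose-binding lectin gene Mbl1 were among those that fell. The calls of Got1 (0.77, adjusted p = 0.166) and Otc (-0.42, adjusted p = 0.187) were lost without fenofibrate libraries 1 and 3.

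Of 16 male-biased genes, 9 fell and 0 rose (10 and 0 adjusted over the list alone; camera adjusted p = 3.7e-06, adjusted p = 0.449 with an estimated correlation). Mup7 fell from 6932 ± 1036 to 1601 ± 1083 CPM (-2.11 ± 0.38), Mup21 (-1.70 ± 0.22) and Hsd3b5 (-1.54 ± 0.33) fell, and so did Ugt2b1 (-1.54 ± 0.27), a glucuronosyltransferase. The Mup genes together took 2.91% ± 0.283 of counts in HFD and 1.09% ± 0.364 with fenofibrate (exact permutation p = 0.0286, 0.172 adjusted over 18 measures), against 1.81% ± 0.247 in Control. Of 9 female-biased genes, 4 rose and 1 fell (4 and 1 adjusted over the list alone; camera adjusted p = 0.0936), the rising ones including Cux2 and Cyp2b9. B and plasma cell markers summed to 48.7 ± 6.90 CPM in HFD and 29.2 ± 4.30 with fenofibrate (exact permutation p = 0.0286, 0.172 adjusted).

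Genes of fatty acid oxidation and other known PPARA targets moved both ways. Of 23 peroxisomal beta-oxidation genes, 3 rose and 7 fell (3 and 7 adjusted over the list alone; camera adjusted p = 0.0153, direction down, adjusted p = 0.926 with an estimated correlation), with Crot falling from 1370.5 ± 196 to 574 ± 29.0 CPM (-1.26 ± 0.20, adjusted p = 0.00225) and Abcd3 at -0.79 ± 0.15. Of 22 mitochondrial beta-oxidation and ketogenesis genes, 1 rose and 3 fell (1 and 10 adjusted over the list alone; camera adjusted p = 0.0153, adjusted p = 0.926 with an estimated correlation), with Acad11 at -0.58 ± 0.12. Both camera calls were lost without HFD library 4 (adjusted p = 0.0585) or fenofibrate library 2 (adjusted p = 0.0556). None of the 11 microsomal omega-oxidation genes passed in either direction, over all genes tested or adjusted over the list alone (camera adjusted p = 0.555). Its most abundant members were Cyp4a14, at 4979.9 ± 268 CPM with fenofibrate and 2403 ± 1004 in HFD (1.05 ± 0.39, adjusted p = 0.0844), and Cyp4a10 (0.49 ± 0.22, adjusted p = 0.149), close copies whose reads can be split. Among 24 other PPARA targets, 3 rose and 4 fell (3 and 7 adjusted over the list alone; camera adjusted p = 0.311), Slc27a1 and Por (1.05 ± 0.17) rising and Fabp1 (-1.46 ± 0.22) and Angptl4 (-1.11 ± 0.21) falling.

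Of 16 lipid droplet genes, 4 rose and 4 fell (4 and 5 adjusted over the list alone; camera adjusted p = 0.526). Besides the falls of Plin2 and G0s2, Pnpla2, the main triglyceride lipase, rose from 75.8 ± 9.35 to 130.4 ± 25.2 CPM (0.78 ± 0.16, adjusted p = 0.00586), and Mogat1, a monoacylglycerol acyltransferase, rose (2.05 ± 0.40). Of 20 genes of lipoproteins and plasma lipid handling, 3 rose and 5 fell (5 and 5 adjusted over the list alone; camera adjusted p = 0.54). Lpl, the lipase of circulating triglycerides, rose from 19.8 ± 2.54 to 62.9 ± 28.9 CPM (1.67 ± 0.27, adjusted p = 0.00196), and Apoa4 fell (-1.02 ± 0.19). Calls of Pnpla2 (0.55), Mogat1 (1.29), Apoa4 (-0.77), Por (0.84), Angptl4 (-0.78), Abcd3 (-0.65) and Acad11 (-0.54) were lost without fenofibrate libraries 1 and 3, where each kept its sign (log2 changes of that fit in brackets, adjusted p from 0.0581 to 0.173). Camera called 5 lists in this comparison, and 31 of the 35 divisions of its 8 libraries called at least as many.

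Of the panel, Plin2, Cyp7a1 and Cd36 (0.75 ± 0.21, 50.5 ± 18.3 to 84.9 ± 10.6 CPM, adjusted p = 0.0299) passed. Not passing were Ppara (-0.19 ± 0.17), Pparg (-0.49 ± 0.18), Ehhadh (-0.67 ± 0.35), Cpt1a (0.29 ± 0.12), Pdk4 (-1.02 ± 0.61), Fgf21 (-1.47 ± 0.54), Cidec (-0.32 ± 0.21), Scd1 (-0.67 ± 0.27), Fasn (0.55 ± 0.21) and Srebf1 (0.45 ± 0.26), with adjusted p from 0.0813 to 0.478, besides Cyp4a10 and Cyp4a14. The Cd36 call was lost without HFD library 4 (adjusted p = 0.0616) or fenofibrate library 1 (0.0629), 3 (0.0743), 4 (0.0765) or 1 and 3 together (0.2, log2 change 0.75). Cyp4a14 passed without Control library 2 (adjusted p = 0.0287) or 3 (0.0494), Fgf21 without Control library 2 (0.0282) or fenofibrate library 2 (0.0454), Fasn without Control library 2 (0.0434) or fenofibrate library 2 (0.0195), and Pparg without HFD library 1 (0.0482). With only the 8 libraries compared Cyp4a14 (0.0203), Fgf21 (0.0282) and Fasn (0.0436) passed, and with no low-count filter Cyp4a14 (0.0321) and Fgf21 (0.0242).

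Fenofibrate livers were also compared with Control livers, which shows how far the treated mice stood from mice on a normal diet. The drug-metabolism gene Cyp3a11 and the complement gene C9 were lower in the treated livers, and the lipogenic gene Pklr and the clock repressor gene Nr1d1 were higher. Cyp3a11 stood at 1591 ± 423 CPM with fenofibrate and 10745 ± 951 in Control (-2.76 ± 0.18, adjusted p = 4.4e-07). Plin2 was at 352 ± 42.2 and 859 ± 358 CPM (-1.29 ± 0.24, adjusted p = 0.00339), and Cyp7a1 at 123 ± 46.9 and 122 ± 71.1 CPM (0.01 ± 0.38, adjusted p = 0.99). In all, 655 genes rose and 581 fell, 150 and 166 of them at least 2-fold. Rising genes numbered 383 without Control library 2, 414 without Control library 4 and 407 without fenofibrate library 3, and falling genes 385 without Control library 2, 336, 310 and 381 without fenofibrate library 1, 3 and 4. Without fenofibrate libraries 1 and 3 the counts were 215 and 158.

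Under the naming rule, which asks for a mean of 10 CPM in the higher group, rises were largest in Cyp2b9 (8.97 ± 0.87, with 13 reads in Control), Dbp (4.67 ± 0.53), Cyp2a22 (4.41 ± 0.39), Rgs16 (4.26 ± 0.61), Rad51b (4.06 ± 0.44), Nr1d1 (3.14 ± 0.21), Vldlr (3.03 ± 0.35) and Tpm2 (2.97 ± 0.56), a tropomyosin gene also expressed in skeletal muscle, whose call was lost without fenofibrate libraries 1 and 3 (1.303, adjusted p = 0.0785). Falls under that rule were largest in Cyp2c55 (-3.18 ± 0.20), Cyp3a11, Gsta2 (-2.74 ± 0.26), Ces2c (-2.45 ± 0.27), CT010575.3 (-2.35 ± 0.52), Mup1 (-2.26 ± 0.35), Ugt1a9 (-2.23 ± 0.18) and Cib3 (-2.16 ± 0.42). Adjusted p for these 16 genes lay between 4.4e-07 and 0.0107. Without 1 library the log2 change of Cyp2b9 was 9.90 (Control library 4) and that of Rad51b 5.03 (Control library 2), and the CT010575.3 call was lost with DESeq2 (adjusted p = 0.067) and without fenofibrate libraries 1 and 3 (0.116, log2 change -2.23).

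Of 28 xenobiotic metabolism genes, 14 fell and 3 rose (18 and 4 adjusted over the list alone; camera adjusted p = 1.7e-09, adjusted p = 0.114 with an estimated correlation), Cyp2c38 (1.24 ± 0.19) being among those that rose. Of 26 amino acid catabolism genes, 7 fell and 0 rose (12 and 0 adjusted over the list alone; camera adjusted p = 9.5e-06, adjusted p = 0.695 with an estimated correlation), among them Got1 (-1.32 ± 0.23), Cth (-1.24 ± 0.21) and Aass (-0.68 ± 0.13), a lysine-degrading enzyme. Of 31 complement and coagulation genes, 9 fell and 1 rose (12 and 1 adjusted over the list alone; camera adjusted p = 9.5e-06, adjusted p = 0.695 with an estimated correlation), with C9 at -1.06 ± 0.16 and C8b at -0.99 ± 0.13. Of 16 oxidative stress genes, 2 fell and 0 rose (4 and 0 adjusted over the list alone; camera adjusted p = 0.00323, adjusted p = 0.695 with an estimated correlation), Mt1 (-2.04 ± 0.28) and the glutathione peroxidase gene Gpx1 (-0.56 ± 0.12). Of 12 hepatocyte markers, 1 fell and 0 rose (4 and 1 adjusted over the list alone; camera adjusted p = 0.0105, adjusted p = 0.696 with an estimated correlation), which was Cyp3a11. The Gpx1 call was lost without fenofibrate libraries 1 and 3 (-0.48, adjusted p = 0.132).

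Of 25 lipogenesis genes, 7 rose and 0 fell (9 and 2 adjusted over the list alone; camera adjusted p = 0.00323, adjusted p = 0.695 with an estimated correlation), including Srebf1 (1.31 ± 0.27, 61.2 ± 21.5 to 152 ± 41.2 CPM) and the pyruvate kinase gene Pklr (0.99 ± 0.14, adjusted p = 7.8e-04). The Srebf1 call was lost without fenofibrate libraries 1 and 3 (1.20, adjusted p = 0.0646). Of 22 mitochondrial beta-oxidation and ketogenesis genes, 6 rose and 0 fell (7 and 1 adjusted over the list alone; camera adjusted p = 0.0267, adjusted p = 0.924 with an estimated correlation), with Bdh1 at 0.80 ± 0.14 and Hadh at 0.52 ± 0.09. That camera call was lost without Control library 1 (adjusted p = 0.222), Control library 3 (0.182) or fenofibrate library 2 (0.0565). Of 18 clock genes, 10 rose and 5 fell (11 and 6 adjusted over the list alone; camera adjusted p = 0.0119, adjusted p = 0.695 with an estimated correlation), Arntl at -1.70 ± 0.24 and Npas2 at -2.18 ± 0.44 falling. Of 16 male-biased genes, 7 fell and 1 rose (8 and 2 adjusted over the list alone; camera adjusted p = 0.00323, adjusted p = 0.696 with an estimated correlation), Mup7 (-1.81 ± 0.38) falling and Hsd3b5 (1.59 ± 0.33) rising. None of 21 interferon response genes passed in either direction, over all genes tested or adjusted over the list alone, with edgeR (camera adjusted p = 0.0105, adjusted p = 0.924 with an estimated correlation). The interferon call was lost without Control library 1 (adjusted p = 0.333), Control library 4 (0.104) or fenofibrate library 1 (0.0805), and without fenofibrate libraries 1 and 3 (0.447). Camera called 10 lists, and 14 of the 35 divisions of the 8 libraries called at least as many.

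In the panel, Cd36 rose from 26.1 ± 1.13 to 84.9 ± 10.6 CPM (1.70 ± 0.22, adjusted p = 3.2e-04), and Srebf1 rose as given. Fasn, the fatty acid synthase gene (0.90 ± 0.21, adjusted p = 0.0157), and Scd1 (0.93 ± 0.27, adjusted p = 0.0452) passed narrowly. Not passing were Ppara (0.29 ± 0.17), Pparg (0.03 ± 0.19), Ehhadh (-0.78 ± 0.35), Cyp4a10 (0.17 ± 0.22), Cyp4a14 (0.88 ± 0.39), Cpt1a (0.02 ± 0.12), Pdk4 (-1.84 ± 0.61), Fgf21 (-0.42 ± 0.56), Cidec (-0.64 ± 0.20) and Cyp7a1. The Fasn call was lost without fenofibrate library 3 (adjusted p = 0.0538) or 4 (0.0505) or without libraries 1 and 3 together (0.16, log2 change 0.77), and the Scd1 call without any 1 of the 4 Control libraries, HFD library 2 or 4 or fenofibrate library 1, 2 or 4 (0.0511 to 0.131), with limma-voom (0.0808) or with a filter of at least 1 CPM on average (0.0518). Without Control library 2, Cyp4a14 passed (1.49, adjusted p = 0.0151), Fgf21 stood at 0.52 and Pdk4 at -1.12 (adjusted p = 0.285). Cidec passed without HFD library 3 or 4 (adjusted p = 0.0497 in both), with DESeq2 (0.0315) and with no low-count filter (0.0491). Pdk4 passed without HFD library 3 (adjusted p = 0.0427), with no low-count filter (0.00817) and with only the 8 libraries compared (0.0316).

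**Figure D2:**
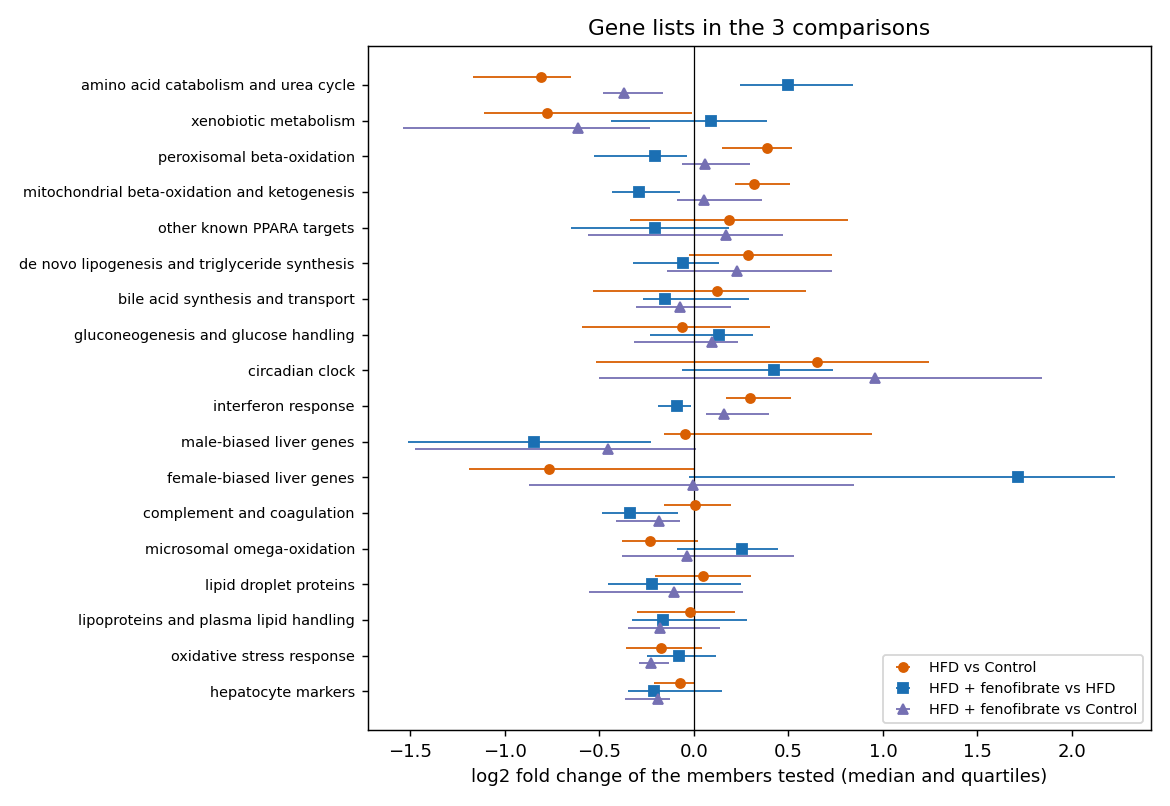
Median log2 fold change of the members tested in 18 gene lists, with lines from the lower to the upper quartile, for HFD against Control, HFD plus fenofibrate against HFD and HFD plus fenofibrate against Control. The amino acid list has a median of -0.81 with the diet and 0.50 with fenofibrate.

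Many genes that the diet changed moved the other way with fenofibrate. Of the 1721 genes changed by diet, 644 (37.4%) were called in the opposite direction with fenofibrate, 300 that had risen and 344 that had fallen, and 20 moved further in the same direction. Asl, Got1, Por and Mt1 fell with the diet and rose with fenofibrate, whereas Mup17, Crot, Fabp1 and Hsd3b5 rose with the diet and fell with fenofibrate. Cyp2b9 rose in both. Of the 644, 57 were still called against Control and 587 were not, which does not show that they returned to the Control level. A further 1152 genes called with fenofibrate (63.4%) had not been called with the diet.

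Both comparisons use the HFD libraries, which alone makes their values run opposite. Independent lists of these sizes would share 116 genes in opposite directions. Across genes, which are not independent replicates, the log2 fold changes had Pearson r = -0.528 and Spearman rho = -0.533, where 20 simulations of groups with no effect gave a mean r of -0.504 and rho of -0.47. The covariance was -0.11, against -0.0262 simulated. With the HFD libraries divided 2 and 2 between the comparisons, in all 6 assignments, 72 to 196 genes moved back (median 143, against 10.8 expected of independent lists), with a median r of -0.302 and a median covariance of -0.117. The count was 348, 385 and 339 without HFD library 1, 2 and 4, 389 and 308 without fenofibrate library 1 and 3, and 87 without both of the latter.

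**Figure D3:**
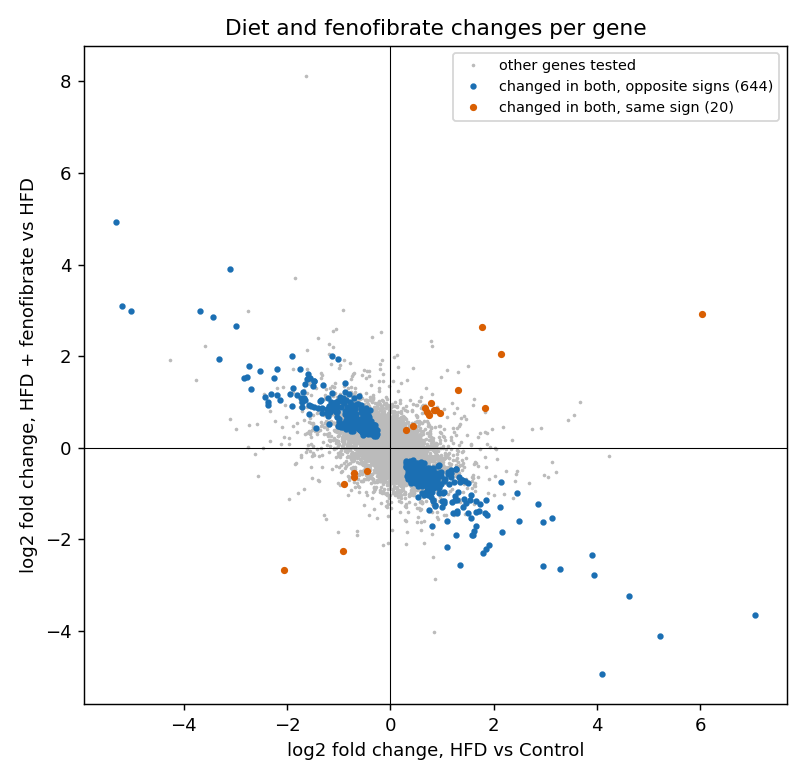
Log2 fold change of each of 13477 genes for HFD against Control (horizontal) and HFD plus fenofibrate against HFD (vertical), both fitted with the same HFD libraries. Blue points are the 644 genes called in both comparisons with opposite signs, orange points the 20 called with one sign, and grey points all others.

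The authors' deposited table of the diet comparison marks 416 genes as significant, 199 higher and 217 lower. The smallest log2 fold change among them is 1.003 in size, so the marking appears to ask for a 2-fold change, which the calls here do not. At adjusted p under 0.05 alone, that table holds 1703 genes. Of the 416 marked genes, 387 were tested here and 373 (89.7% of those marked) were called here with the same sign. For fenofibrate against HFD, the authors' deposited table marks 285 genes, 147 higher and 138 lower, of which 249 were tested here and 226 (79.3% of those marked) were called here with the same sign. The smallest log2 fold change among those marked is 1.002 in size, and 2568 genes have an adjusted p under 0.05 in that table. None of the marked genes tested here had the opposite sign in either comparison. Both sets of fold changes come from the same counts (r = 0.99995 and 0.99994 over genes), so the shared signs are not an independent check.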

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

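The tests of explanations below were chosen after the results were seen. A library is listed where its gap to the nearest other library of its group, divided by the group's range, exceeds Dixon's 95% critical value for 4 libraries, which happens by chance in about 1 in 20 groups. Among the genes covered, 19 of 318 groups exceeded it, with 15.9 expected by chance, and among the values per library 3 of 57 did.

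For whole-library values, HFD library 1 had a mitochondrial share of 10.59% (others 8.784% to 8.873%) and 336.8 CPM of endothelial markers (619.4 to 648.6), and fenofibrate library 1 had 2154 CPM of pancreatic acinar markers. Control library 2 stood apart, at 485.0 CPM, in G0s2 (others 151.5 to 181.9), at 110.6 CPM in Pdk4 (28.0 to 34.51), at 1236 CPM in Acaa1b and at 20.56 CPM in Apoa4. Control library 1 was at 398.5 CPM in Akr1c6 and 356.8 in Otc, Control library 3 at 12.25 CPM in Lcn2, and Control library 4 at 0.498 CPM in Cyp2b9 and 462.0 in Got1. HFD library 2 was at 76.92 CPM in Rgs16 (16.13 to 22.69), HFD library 3 at 36.83 CPM in Cyp2b9 (2.43 to 7.892) and 4.235 in Vldlr, and HFD library 4 at 62.3 CPM in Mup1. Fenofibrate library 2 was at 163.8 CPM in G0s2 (51.2 to 60.34) and 39.23 in Pltp, and fenofibrate library 4 at 221.8 CPM in Acad11, 18.09 in Lipg, 121.3 in Pex11a and 6.8 in Ugt1a9. Control library 2 and fenofibrate library 4 had 4 such genes each.

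Pancreatic and striated muscle transcripts appeared in treated libraries. Of the 12 acinar markers, 11 were over 10 times higher in fenofibrate library 1 than in any other library, with Pnlip at 291 CPM and Cpa1 at 259 CPM, which is consistent with pancreatic tissue in that sample. Induction by fenofibrate is argued against, since the 11 markers other than Cela1, which every library holds, summed to at most 0.73 CPM in the other treated libraries, below the highest untreated library at 0.86 CPM, with Cpa1 at most 0.05 CPM there. The lower of the striated muscle sums of libraries 1 and 3 was 122.47 CPM, against 1.03 CPM at most elsewhere, so striated muscle in both samples stays open. Fenofibrate changes confined to libraries 1 and 3 are argued against by the changes in libraries 2 and 4, which followed them over genes with a median r of 0.591 (0.494 to 0.638 over 6 ways to divide the HFD libraries; genes are not independent replicates).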

How the results depend on the processing

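The fits without fenofibrate libraries 1 and 3 and with a clock score were chosen after the results were seen. Of 147 single-gene results under the naming rule that passed, 118 stayed past the threshold in each of the 20 or 21 alternatives chosen beforehand and 29 were lost in at least 1; of 36 that did not pass, 10 passed in at least 1, and 0 that passed had the opposite sign in any of these. Counts of rising and falling genes at 2-fold were 185 and 217 (diet), 136 and 118 (fenofibrate against HFD) and 150 and 166 (fenofibrate against Control), with 93 moved back and 5 further, and at adjusted p under 0.01 they were 343 and 360, 200 and 262, and 235 and 219, with 173 back and 3 further; these thresholds are stricter by construction. Genes moved further numbered 40 with DESeq2 and 13 with limma-voom. With a replicate block the counts were 746 and 765, 805 and 869, and 570 and 534, with 573 moved back and 23 further. Leaving out each library in turn gave 550 to 832 rising and 554 to 930 falling with the diet, 282 to 1210 and 328 to 1206 with fenofibrate against HFD, 383 to 858 and 310 to 852 against Control, 308 to 707 moved back, 9 to 34 further, r from -0.572 to -0.457, and 7 to 9, 3 to 9 and 9 to 12 lists called. Without fenofibrate libraries 1 and 3 the counts were 55 and 69 against HFD and 215 and 158 against Control, with 87 back, 2 further, 13 lists against HFD and r = -0.484; without Control library 2 as well they were 64 and 81, and 161 and 138, with 100 back, 4 further and 13 lists. Other pairs of treated libraries left out gave 258 to 1859 calls. With the clock score as a covariate the counts were 149 and 108, 273 and 279, and 2 and 3, with 61 back and 7 further; the score follows Control against the rest (r = 0.913), so the fits against Control lose group differences by construction, whereas the cause of the drop for fenofibrate against HFD was not tested. With it these changes reversed in sign, none past the threshold: with the diet Arntl 0.11, Npas2 0.79, Cd36 -0.32 and Srebf1 -0.62; against Control Srebf1 -0.59, Cth 0.013, Aass 0.004, C4b -0.23, Npas2 0.99, Arntl 0.52, Plin2 0.12 and Fasn -0.38. With an estimated correlation camera called 0, 0 and 0 lists. Fry called 6 against Control. With the diet, fry adjusted p was 2.85e-04 for amino acid catabolism and 2.96e-04 for xenobiotic metabolism. It was 0.0235 and 0.031 for peroxisomal and mitochondrial beta-oxidation, and 0.0395 for oxidative stress and for hepatocyte markers. For fenofibrate against HFD it was 0.00673 for complement, 0.00712 for amino acid catabolism, 0.0236 for male-biased and 0.0269 for female-biased genes. No other list passed fry in either comparison. Over genes called with the diet r was -0.694, over genes called in either comparison -0.599. With the HFD libraries divided, medians were 143 moved back, 7.5 further and r = -0.302, with fewer libraries by construction. Where no construction is named, the cause was not tested. Alternatives for normalized values (pseudocount, filter, FPKM) were not run, since the values are counts. At this depth and spread, simulated 1.5-fold changes with the diet were recovered in 26.9% of genes, so smaller changes can be missed.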

Other observations

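The tests of explanations and the term counts in this part were chosen after the results were seen, and the limits for the divisions of the libraries were also written after them. Gene Ontology terms of 10 to 200 genes were counted among called genes, with the 11364 annotated genes outside the Mup family as background. Genes that rose with the diet were enriched for fatty acid beta-oxidation (13 of 37 genes, adjusted p = 1.4e-04, hypergeometric test over 1650 terms). Genes that fell with fenofibrate against HFD were enriched for the alternative pathway of complement (9 of 17, adjusted p = 4.5e-04) and for flavonoid glucuronidation (8 of 15, adjusted p = 6.6e-04), the latter made of Ugt2 and Ugt3 copies whose reads can be split. Genes that fell against Control were enriched for the epoxygenase P450 pathway (10 of 26, adjusted p = 9.4e-05). With the Mup family included, 25 terms were called among genes that fell with fenofibrate against HFD, and 8 without it, since 25 of 27 Mup genes and pseudogenes fell. The hypergeometric test treats genes as independent. In the fixed lists, members were correlated, at 0.269 and 0.449 for the beta-oxidation lists with the diet. For complement and coagulation with fenofibrate against HFD the estimate was 0.174, so these adjusted p-values can be too small.

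Divisions of the libraries tested whether chance could give as many calls. In fits of the 8 libraries compared alone, the real groups gave 1393 genes for the diet (highest other division 0), 2287 for fenofibrate against HFD (highest other 1) and 951 for fenofibrate against Control (highest other 637), each 1 of 35 divisions. This is the smallest share that the divisions can give, so they argue against chance at that share and no further. Other divisions mix the real groups, so a real difference adds to their spread and lowers their calls. The 637 came from Control library 1 placed with fenofibrate libraries 1, 3 and 4, which points to a structure among these libraries beside the groups. For the number of lists, 24, 31 and 14 of 35 divisions gave as many as the real 7, 5 and 10 (highest others 14, 13 and 14), so chance is not excluded. Among the lists called, divisions with a camera p as small, the real one included, differed by list. With the diet they were 1 of 35 for amino acid catabolism and for xenobiotic metabolism, and 3 to 14 for the rest. With fenofibrate against HFD they were 1 for complement and coagulation, 4 for amino acid catabolism and for male-biased genes, and 6 and 7 for the rest. Against Control they were 1 for xenobiotic metabolism and for complement, and 3 to 18 for the rest. Some of these ranks were near ties. For complement with fenofibrate against HFD the real camera p was 5.37e-06 and the smallest other 5.64e-06. For xenobiotic metabolism against Control they were 2.67e-10 and 3.43e-10. Of 100 groupings of the 12 libraries, 1, the real one, gave as many genes moved back as 644 (highest other 0). None of the other 99 called a gene in both comparisons with edgeR (at most 1168 and 438 in either), so they could not have given a gene moved back, and this says nothing on whether fenofibrate reverses the diet's changes beyond the shared HFD libraries. An r as low as -0.528 came from 43 of the 100 (lowest other -0.766), and a covariance as low as -0.1102 from the real one alone, 1 of 100 (lowest other -0.1021).

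Clock genes separated Control from both high-fat groups. With the diet, 14 of 15 genes in the clock's arms had a fitted change of the sign that a shift in phase predicts, passing or not, which is consistent with such a shift. The highest clock score of a Control library was -1.837, below the lowest of the others, -0.168. Collection of the Control livers at another time of day and an effect of the diet on the clock cannot be told apart, since the score follows the groups. With the score as a covariate 3 of 26 amino acid catabolism genes fell, with a median log2 change of -0.57 against -0.81 without it, and for the same reason clock phase as a cause of their fall cannot be told apart from the diet.

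Of 16 male-biased genes, 9 fell with fenofibrate against HFD. Reads shared between Mup copies do not bear on the other 13 members, whose median log2 change was -0.624 with 6 past the threshold. Sharing that only moves reads between copies would leave the total of the Mup family unchanged. The counting settings are not given, so reads matching several copies may instead have been left out. The family total therefore does not decide whether such sharing played a part. The family took 2.62% to 3.27% of counts in HFD libraries and 0.737% to 1.52% with fenofibrate. For single Mup genes shared reads stay open. A female or exchanged female sample is argued against by Xist at 0.286 CPM or below and Ddx3y at 32.1 CPM or above in every library. Fewer hepatocytes are argued against by the hepatocyte markers, with a median of -0.213 and a lower quartile of -0.351, against a median of -0.845. No biological explanation was tested.

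Fenofibrate activates PPARA, which would predict a general rise of its target genes. Of 80 tested members of the 4 lists of fatty acid oxidation genes and other PPARA targets, 7 rose and 14 fell with fenofibrate against HFD. Their median log2 change was -0.194, which argues against a general rise above the HFD level in these libraries. The oxidation lists are whole pathways and not only PPARA targets. With the diet alone, 10 peroxisomal, 7 mitochondrial, 1 omega-oxidation and 9 other genes had risen, and 0, 0, 3 and 1 had fallen. Against Control, 3, 6, 2 and 8 rose with fenofibrate, and 0, 0, 3 and 4 fell. Rises of single targets, as of Slc27a1, are not excluded by the count against HFD.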
